A study of Homo sapiens with 2 samples.

How the data were processed

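The series holds 2 samples, both SRSF1 HITS-CLIP libraries of H1299 cells, numbered as replicates 1 and 2 of 1 group. H1299 is an established human non-small cell lung carcinoma line, and SRSF1 is an SR-family splicing factor that binds RNA. In HITS-CLIP, ultraviolet light crosslinks a protein to the RNA it touches in living cells, the protein is immunoprecipitated with its RNA, and the RNA fragments left after trimming (tags) are reverse transcribed and sequenced. A residual peptide on the RNA can make the reverse transcriptase stop, which gives a truncation site, or misread the base, which gives a mutation site. The labels list no control library.

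Per the submitters' processing notes, the tools included cutadapt, for which no version is given, and BWA 0.7, and the genome build was hg19. The settings of the aligner, the treatment of PCR duplicates and of reads with several possible places, and the step at which the replicates were combined are not given in the sources used here. The authors deposited 1 list of 6754 sites for the series, with no column for either replicate, so no replicate spread, SD or test between samples could be computed. Each line gives an interval of 21 nt (6740 sites) or 22 nt (14 sites), a strand, a tag count and a name. The row names follow the CTK toolkit, which the list is named after; the meaning given to each abbreviation here follows that naming and is not stated in the labels. A truncation site carries the count of tags truncated there (PH), the number expected per position of its tag cluster (PH0) and a P. A mutation site carries the tags covering it (k) and the tags mutated there (m). The tag count that the authors deposited equalled PH or m in all 6754 lines, so the counts of the 2 kinds are not on 1 scale and were compared within a kind, except in the ranking of named sites and in the alternative settings that keep sites by tag count. The kind of mutation (deletion or substitution) is not given in the list. The total number of tags per library is unknown here, which limits any statement about sites that are missing from the list.

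Values computed here were the following. Positions are 1-based hg19 positions as the intervals give them, and the distance between sites was taken between interval midpoints, counted 5′ to 3′ on the site's strand. Sites on 1 strand with gaps of at most 1000 nt were joined into loci. For proximity, the mutation sites within 10, 25 or 50 nt of a truncation site were counted and set against 1000 draws in which each mutation site was moved by a random 100 to 1000 nt in a random direction. Sides (5′ or 3′ of the nearest truncation site, or of every truncation site in range where pairs were counted) were compared by an exact two-sided binomial test. Medians were compared by two-sided permutation tests with 100000 resamples, whose smallest possible value is 2e-05. Shares carry exact Clopper-Pearson 95% intervals. These intervals and tests treat sites, pairs of sites or loci as units of 1 list, cover counting error only, and say nothing of the spread between experiments. Cluster numbers in the names never decreased along a chromosome strand (0 decreases), so the highest number on each strand was read as a lower bound on how many clusters had been numbered there. Chromosomes were compared by loci per 100 protein-coding genes, with the gene number per chromosome counted in GENCODE v29, by an exact two-sided binomial test of the loci with Benjamini-Hochberg adjustment over 24 nuclear chromosomes. The counting of distances and sides was checked on simulated data with the 4731 real truncation sites. Of 200 mutation sites planted within 10 nt, with 80% on the 3′ side, 200 sites were found within 10 nt, 80.5% of them 3′. With the sides planted alike, 202 were found, 49.0% of them 3′. With none planted, 2 of the 2023 sites were within 10 nt. Planted sites lay in the window by construction, and the other mutation sites were moved much farther than in the draws. The check therefore covers the counting alone, and not how shared coverage acts on the comparison with displaced sites.

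The annotation at hand is for GRCh38. On 12 of the 25 chromosome sequences a site lies beyond the last gene of that annotation, so none of its positions were used with the hg19 sites, and no genome sequence was used. The planned assignment of sites to exons, introns and genes, the distances to splice sites, the motif tests, the heights by region and the 14 gene lists were therefore not run, and 13 of the 15 processing choices for which alternatives were set in advance belong to them. The rule fixed before the data were examined for this case names the 10 sites with the highest tag count by position. The loci described were chosen after their values were seen: in the report the 5 with the most sites, a neighbour of 1 of them and the one on the mitochondrial plus strand, and in the closing section examples among loci of at most 500 nt. The comparison of the 2 kinds of site, the loci and the chromosome comparison were added after the list was read. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.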

Results

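SRSF1 crosslink sites in H1299 cells were listed as 1 set of 6754 positions from 2 HITS-CLIP replicates. The question that the design implies is where on cellular RNA this splicing factor is crosslinked. Truncation sites made up 4731 of the positions (70.0%, 95% interval 68.9 to 71.1%) and mutation sites the other 2023. The plus strand held 3426 sites (50.7%, 49.5 to 51.9%) and the minus strand 3328. The list spanned 22 autosomes, X, Y and the mitochondrial sequence. The replicates are not separated in the list, so every value below is a value of the combined list and has no replicate check.

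Truncation sites rested on few tags, though on several times the number expected per position. The median site had 6 truncated tags (quartiles 5 and 9, range 4 to 42), against a median of 0.19 tags expected per position of its cluster. The ratio of observed to expected tags had a median of 35.3 (quartiles 26.1 and 44.4) and ran from 5.31 to 100. No listed site had under 4 truncated tags, so a low expected number came with a high ratio by selection. The authors' P for these sites had a median of 1.24e-05 and a highest value of 0.001, and 140 sites stood at the lowest listed value of 1e-100. The 4731 sites lay in 4370 tag clusters, of which 4112 (94.1%) held 1 site, 206 held 2 and 52 held 3 or more. The cluster numbers reached 533276 when the highest number of each chromosome strand was summed, so at most 0.819% of the numbered clusters held a truncation site. Within clusters, neighbouring truncation sites were a median of 53 nt apart (quartiles 37 and 82, over 361 gaps) and never closer than 26 nt. The settings used to call the sites are not given, so these spacings and the number of sites per cluster may reflect the calling.

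Mutation sites were mostly shallow. The median site was covered by 5 tags (quartiles 3 and 8, range 2 to 503), of which 2 were mutated (quartiles 2 and 3, range 2 to 73). Of the 2023 mutation sites, 462 (22.8%) rested on 2 tags that were both mutated. The list held no site with under 3 mutated tags once 10 or more tags covered it, and none with under 4 once 32 or more did. The median mutated share was 33.3% of tags at 5 to 9 covering tags, 14.3% at 20 to 49 and 6.02% at 50 or more. The smallest number of mutated tags in the list sets much of this order. At 2 to 4 covering tags the share could not fall under 50%, and at 5 to 9 covering tags 494 of the 649 sites had the smallest number, 2.

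Truncation and mutation sites shared some of the same positions. The 2 kinds shared an identical interval at 18 places, against a mean of 0.534 after random displacement. Within 10 nt of a truncation site on the same strand lay 97 mutation sites (4.79%, 3.91 to 5.82%), against 12.7 ± 3.22 (SD over 1000 draws) after displacement, a ratio of 7.66. Within 50 nt lay 332 (16.4%, 14.8 to 18.1%), against 51.2 ± 5.69, a ratio of 6.49. No draw reached the observed number in either window, so the one-sided permutation p was 0.001, the smallest that 1000 draws can give. The moves were not limited to places with tags, and both kinds of site need tags. The excess over displaced sites therefore does not separate shared positions from shared coverage. Without the 10 loci with the most sites the ratio within 10 nt was 15.7. Seen from the other kind, 321 truncation sites (6.79%, 6.08 to 7.54%) had a mutation site within 50 nt. Proximity was strand-specific. Of the pairs within 500 nt, 1068 were on the same strand and 1 was on opposite strands. Most sites of each kind stood alone all the same: 3324 loci held truncation sites alone, 1461 held mutation sites alone and 414 held both.

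Around a truncation site the mutation sites were not placed evenly, in bands of distance chosen after the data were seen. The first group lay at the truncation site or just 5′ of it, with 18 pairs at distance 0. By nearest truncation site, 33 mutation sites lay 1 to 4 nt 5′ and 11 lay 1 to 4 nt 3′ (exact binomial p = 0.00126). The second group lay farther 3′, with 218 pairs from 8 to 50 nt 3′ against 69 in the same band 5′. Taking each mutation site's nearest truncation site, 224 lay 1 to 50 nt 3′ and 90 lay 5′, a ratio of 2.49 (1.94 to 3.22, exact binomial p = 2.46e-14). From 51 to 100 nt the pairs were 69 and 65 (exact binomial p = 0.796), and beyond 100 nt, up to 500 nt, they were 316 on the 3′ side and 255 on the 5′ side (ratio 1.24, 1.05 to 1.47, exact binomial p = 0.0120). A mutation site enters these counts once per truncation site in range, so the pairs are not independent. These p-values and this interval therefore understate the uncertainty. The 3′ excess lay among mutation sites with 10 or more covering tags, 189 on the 3′ side and 42 on the 5′ side. This split by depth was chosen after the data were seen. Sites with under 10 covering tags went 35 and 48 (exact binomial p = 0.187), and the 2 depth classes differed (Fisher's exact p = 4.03e-11). Among these shallow sites, the ones 1 to 4 nt away were all on the 5′ side, 18 against 0. Those 5 to 50 nt away went 35 on the 3′ side and 30 on the 5′ side. Depth and side are not independent, because at least 4 tags begin at each listed truncation site and cover the bases just 3′ of it. Sites just 3′ thus tend to fall in the deeper class whatever places them. The difference between the depth classes and the 18 against 0 are therefore partly set in advance.

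**Figure D1:**
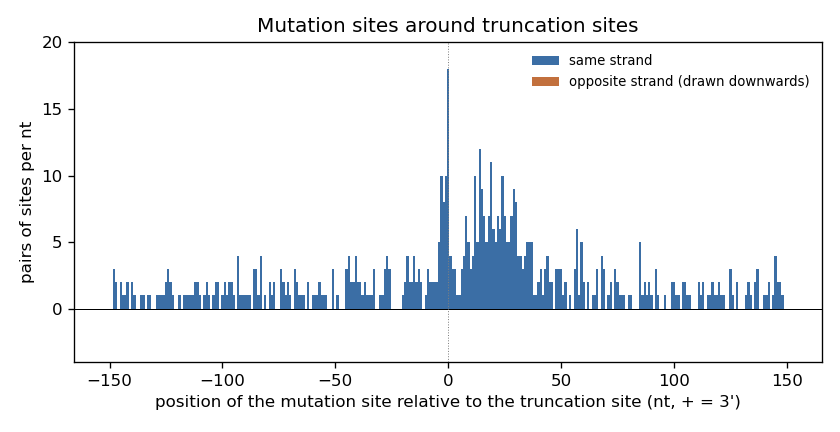
Number of pairs of a mutation site and a truncation site per nt of distance (vertical axis) against position relative to the truncation site in nt (horizontal axis, 3′ positive); same-strand pairs are drawn upwards and opposite-strand pairs would be drawn downwards. The single highest bar is the 18 pairs at distance 0, a shoulder lies just 5′ of it, and a broad group of pairs lies about 8 to 50 nt 3′.

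The share of mutation sites with a truncation site nearby rose with their depth. A truncation site lay within 50 nt of 2 of the 462 mutation sites covered by 2 tags (0.433%, 0.0525 to 1.55%), and of 75 of 649 covered by 5 to 9 tags (11.6%, 9.20 to 14.3%). The share was 75.5% (67.9 to 82.0%) at 20 to 49 tags and 87.5% (78.7 to 93.6%, 77 of 88 sites) at 50 or more. At least 4 tags begin at each listed truncation site and cover the bases just 3′ of it. A mutation site covered by 2 or 3 tags can therefore hardly lie just 3′ of one. Part of the rise, and of the difference in median coverage given below, is thus set by that smallest number. The ratio to displaced sites did not rise with depth. Within 10 nt it was 11.1 at under 10 covering tags and 6.68 at 10 or more, a difference that was not tested. Each ratio was taken to displaced sites of its own depth class, so a ratio that does not rise says nothing against an effect of depth. The 332 mutation sites near a truncation site were covered by a median of 23 tags, against 4 for the 1691 others, and had a median mutated share of 18.6% against 60.0%. At equal coverage, among sites with 10 or more covering tags, the mutated share near minus far was -1.80 percentage points (permutation p = 0.144), a difference that did not pass the test. Truncation sites near a mutation site had more truncated tags (median 8 against 6) and a higher expected number per position (0.29 against 0.19). Their ratio of observed to expected tags was lower, 28.6 against 35.7. Each of these medians without matching for coverage, and that of the mutated tags (4 against 2), differed by a permutation test at its smallest possible p (2e-05, also after Benjamini-Hochberg adjustment over 6 tests). No truncation site in the list had under 4 truncated tags, so a position with 2 or 3 truncated tags is absent from it. A higher expected number therefore allows lower ratios of observed to expected tags among listed sites, and the near and other truncation sites were not matched for it.

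**Figure D2:**
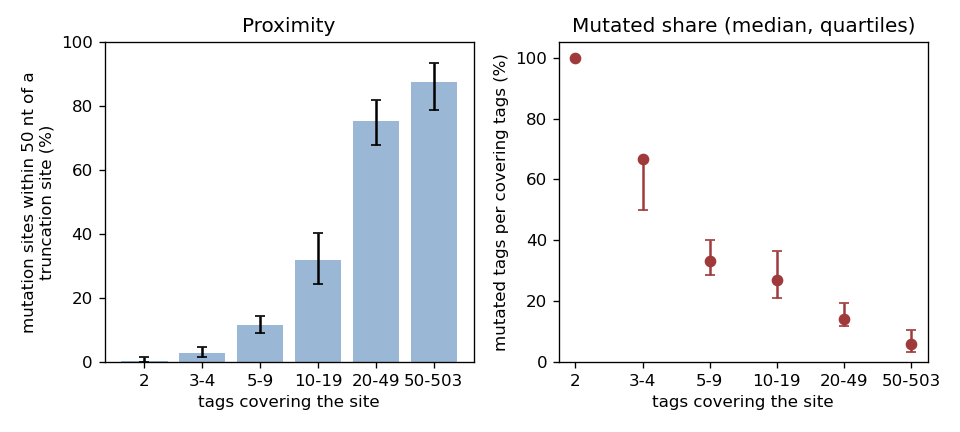
Mutation sites grouped by the number of covering tags (horizontal axis of both panels). The left panel shows the percentage within 50 nt of a truncation site with exact 95% intervals, rising from 0.433% at 2 tags to 87.5% at 50 to 503 tags; the right panel shows the median mutated share with quartiles, from 100% to 6.02%, where at low coverage the smallest number of mutated tags in the list sets the share.

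By the rule fixed in advance, the 10 highest sites were 3 mutation sites and 7 truncation sites. The mutation sites lay on chromosome 12 minus strand (127650918 to 127650938, hg19; 73 mutated of 97 tags, 75.3%), chromosome 5 plus strand (71146902 to 71146922; 60 of 372 tags, 16.1%) and chromosome 2 minus strand (133012602 to 133012622; 35 of 92 tags, 38.0%). Chromosome 16 plus strand held a pair of truncation sites with 42 tags at 33963598 to 33963618 and 35 tags at 33963646 to 33963666, each against 2.11 expected. Chromosome 2 minus strand had 40 truncated tags at 230045590 to 230045610 against 2.64 expected, and 37 at 133039012 to 133039032 against 0.72 expected. The others were chromosome Y plus strand (10035953 to 10035973, 34 tags) and a pair on chromosome 21 plus strand with 33 tags at 9827222 to 9827242 and 32 tags at 9827104 to 9827124. Among 243 mutation sites with 20 or more covering tags, the chromosome 12 site was 1 of 7 with a mutated share of 40% or more. A fixed difference between the cell line and the reference was not excluded there. No gene annotation of the hg19 build was used, so these sites are given by position alone. The treatment of reads with several possible places is not given, so it is unknown whether the tags at these sites arose there or at similar sequences elsewhere.

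Joining sites up to 1000 nt apart on a strand gave 5199 loci. Of these, 4417 (85.0%) held 1 site, 710 held 2 to 4 and 72 held 5 or more, and the 72 loci held 698 sites (10.3% of the list). The locus with the most sites lay on chromosome 11 plus strand, from 65266526 to 65273537. It held 85 sites in 7012 nt, or 1.26% of the list, with 58 truncation sites (median 11 tags, highest 26) and 27 mutation sites (median coverage 73 tags, highest 369). The next was chromosome 15 minus strand, 65243807 to 65247430, with 34 truncation and 2 mutation sites. Chromosome 16 plus strand, 33962596 to 33965862, held 24 and 3. Chromosome 8 minus strand, 144993305 to 145000098, held 26 and 1 over 6794 nt, and a further 8 truncation sites lay 5′ of it on the same strand, at 145001476 to 145003744. Chromosome 21 plus strand, 9825582 to 9827554, was the most evenly mixed of the 5 largest, with 12 of each kind.

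**Figure D3:**
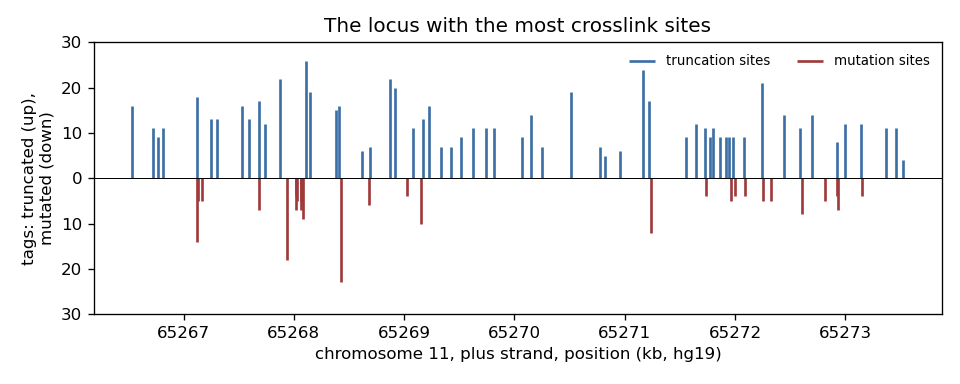
Truncated tags per truncation site (upward lines) and mutated tags per mutation site (downward lines) along chromosome 11 plus strand, hg19 positions in kb, for the locus with the most sites. The 58 truncation sites are spread over the whole 7012 nt, and the highest has 26 tags.

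Chromosomes contributed unevenly for the number of protein-coding genes they carry. Chromosome 8 had 374 sites in 266 loci for 683 coding genes, or 38.9 loci per 100 coding genes, against 26.1 over all nuclear chromosomes. Its share of nuclear loci was 5.12% (4.54 to 5.76%) for 3.43% of the coding genes, a ratio of 1.49 (exact binomial, Benjamini-Hochberg adjusted p = 8.22e-09). At an adjusted p under 0.05, chromosomes 6 (ratio 1.25), 12 (1.25), 7 (1.23) and 2 (1.17) were also above their gene share, making 5 in all. Chromosomes X (0.690), 11 (0.704), 10 (0.805), 3 (0.842), 1 (0.864), 19 (0.881) and Y (0.244) were below it, 7 in all, at an adjusted p under 0.05. Chromosome 11 was low in loci although it held the one with the most sites. The numbered tag clusters on chromosome 8 were at least 34.3 per coding gene, next to lower bounds of 33.4 on chromosome 7 and 32.8 on chromosome 22, which do not rank them. At most 0.952% of them held a truncation site, inside the range of the autosomes (0.531 to 0.986%). On chromosome 20, truncation sites made up 79.9% of 209 sites, the one chromosome whose balance of the 2 kinds differed from the rest (Fisher's exact adjusted p = 0.0311 over 25 sequences). The library depth per chromosome is unknown, and loci on 1 chromosome are not independent replicates.

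**Figure D4:**
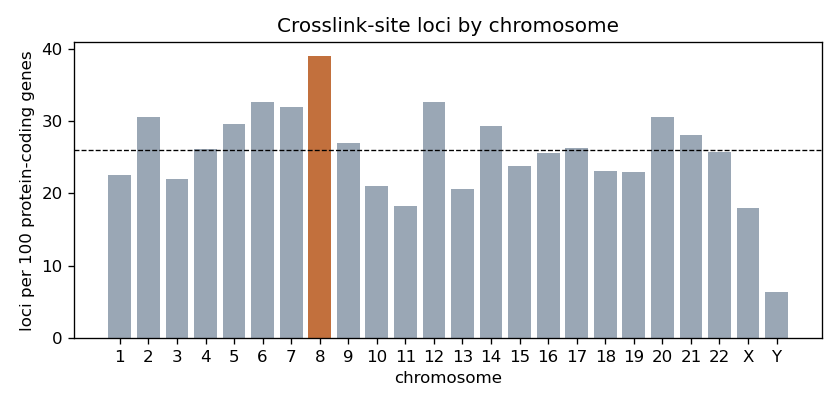
Loci of crosslink sites per 100 protein-coding genes (vertical axis) for each nuclear chromosome (horizontal axis). The dashed line is the value over all nuclear chromosomes, 26.1; chromosome 8, drawn in orange, is highest at 38.9.

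The mitochondrial sequence held 30 sites (0.444% of the list, 0.300 to 0.633%), of which 28 were truncation sites. The plus strand carried 14 truncation sites, and 13 of them lay between positions 917 and 3070 with a median of 10 tags. The minus strand carried 16 sites between 314 and 16000, 14 of them truncation sites. At least 117 clusters were numbered and 26 held a truncation site, at most 22.2%. The same upper bound was 11.1% on chromosome Y (9 of at least 81) and 0.531 to 0.986% on the autosomes, but how far each bound lies above the true share is unknown. Its truncation sites had a higher expected tag number per position than nuclear ones (median 0.315 against 0.19, permutation p = 0.00402). Their ratio of observed to expected tags was lower (median 24.8 against 35.3, permutation p = 5e-04). Every listed truncation site has at least 4 truncated tags, so a higher expected number allows lower ratios, and the groups were not matched for it.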

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

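With 1 combined list, leaving out a replicate was not possible, and no paired analysis was possible because the series has 1 group and its list has no column per replicate. Of 15 processing choices with alternatives set in advance, 13 need an hg19 annotation or genome and were not run, and the alternatives for all results other than the number of sites were chosen after seeing the data. The number of sites, 6754, became 6216 after merging sites within 50 nt, 3175 above the median tag count, 631 in the highest 10% by tag count, and, chosen after seeing the data, 2902 above the median of their own kind. The share of truncation sites moved from 70.0% to 95.9% above the median tag count and 95.6% in the highest 10%, because a mutation site's count is its mutated tags alone and is mostly 2. The share of sites in loci of 5 or more moved from 10.3% to 7.76% with gaps up to 500 nt and to 19.4% with gaps up to 10000 nt. The ratio of mutation sites within 10 nt of a truncation site to displaced ones, 7.66, ran from 6.44 to 15.7 over its 7 alternatives and had a permutation p under 0.05 in each, from fewer draws; the highest value came without the 10 loci with the most sites. The 3′ to 5′ ratio, 2.49, was 2.16 to 4.5 in 7 alternatives and turned to 0.729 for mutation sites with under 10 covering tags, a subset in which the sides did not differ by the exact test (p = 0.187). Chromosome 8 kept a ratio of 1.49 to 1.65 under its 5 alternatives, against 1.62 sites per coding gene relative to all nuclear chromosomes. Depth limits the mutation sites, of which 48.8% rest on 2 to 4 tags.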

Other observations

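The tests of fixed differences in the cell line and of shared spacing, the length limit of 500 nt for loci and the split at 10 covering tags were chosen after the data were seen. Of the 72 loci with 5 or more sites, 13 on 10 chromosomes were at most 500 nt long and held 96 sites. Many sites in few nucleotides need many tags, so a high tag density is part of how these loci were chosen, and no test of their depth against longer loci is given. Chromosome 5 plus strand, 71146747 to 71146922, held 8 sites in 176 nt with coverage of its mutation sites up to 424 tags. Chromosome X plus strand, 108297352 to 108297804, held 8 sites with coverage up to 503. Chromosome 8 minus strand, 70602353 to 70602608, held 10 sites in 256 nt, and chromosome 6 plus strand, 44219877 to 44219915, held 5 sites in 39 nt. Not every such locus was deep: on chromosome 6 minus strand, 72101394 to 72101830, the 1 mutation site was covered by 7 tags and the 4 truncation sites had a median of 6. On chromosome 1 minus strand, 108113126 to 108113605, the 1 mutation site was covered by 3 tags and the 5 truncation sites had a median of 11.

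A candidate explanation for those of the short dense loci with deep coverage is that the loci are copies of 1 repeated sequence that share reads, in which case the spacing of sites could recur. The test used all 13 short dense loci, so it also took in those that were not deep. Among 74 pairs of these loci on different chromosomes, 4 shared 3 sites at 1 alignment. Random placement gave a mean of 2.74 and a highest value of 10 over 1000 placements (one-sided permutation p = 0.283). The test leaves the explanation open, because reads kept only where copies differ would leave different spacings, and no genome sequence was used to compare the loci. No biological explanation was tested.

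The excess of mutation sites 3′ of truncation sites may come from coverage: a tag that begins at a truncation site covers the bases 3′ of it, and mutations are called more easily where tags are many. The 3′ sites were covered by a median of 25 tags and the 5′ sites by 9, a difference of 16 (permutation p = 2e-05, the smallest possible). At least 4 tags begin at each listed truncation site, so coverage is raised 3′ of it whatever places the mutation sites. The difference was therefore largely set in advance and cannot decide whether coverage is the cause. The counts below that split sites by covering tags have the same limit. The excess was also present at 50 or more covering tags, with 53 sites on the 3′ side and 18 on the 5′ side. At under 10 covering tags the ratio of 0.729 (exact binomial p = 0.187) came from sites 1 to 4 nt away, 0 on the 3′ side against 18, while from 5 to 50 nt the sites went 35 against 30. A few dense loci as the whole cause are argued against, since with 1 vote per locus 174 loci had a 3′ majority and 63 a 5′ majority, a ratio of 2.762 (2.06 to 3.75). The group of mutation sites at and just 5′ of truncation sites is not covered by the coverage account. The smaller 3′ excess beyond 100 nt (316 pairs against 255, which are not independent) was not tested against it, and no biological explanation was tested.

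Mutation sites with many covering tags lay near a truncation site more often than those with few. Within 10 nt the share was 0.216% at 2 covering tags and 28.4% at 50 or more. At least 4 tags begin at each listed truncation site, so a mutation site covered by 2 tags can hardly lie just 3′ of one. Part of this rise is therefore set in advance. Sites with under 10 covering tags were 11.1 times as frequent within 10 nt as displaced ones. That ratio is to displaced sites of the same depth class, so it does not weigh against depth. Depth alone is a candidate explanation, because both kinds of site need tags, and no biological explanation was tested. At equal coverage of 10 or more tags, the mutated share of 142 near sites minus that of 140 far sites was -1.796 percentage points. The permutation p was 0.144 within 29 coverage values, from 10000 resamples. This leaves depth alone open. The comparison is of mutated shares and not of nearness to truncation sites, so it could not decide on depth. Fixed differences from the reference would put about 50% or all of the tags in the mutated class where a position has 1 or 2 copies. Among the 243 sites with 20 or more covering tags, 2.881% reached a mutated share of 40% (1.17 to 5.84%). This argues against fixed differences at such shares as the source of most deep sites. Copy number in these cells and reads shared between similar sequences were not examined, so fixed differences at lower shares remain open. Of the 987 sites with 2 to 4 covering tags, 100% reach a mutated share of 40% by construction, so fixed differences, sequencing errors and crosslinks cannot be told apart there.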
